A study of Homo sapiens with 6 samples.

How the data were processed

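Transcriptomes of the 83 cell line were compared between control cells and cells with ApoD overexpression, with 3 libraries in each group. Per the labels' protocols, total RNA was extracted with an RNeasy Plus Mini kit and sequencing libraries were made with a SMARTER mRNA-Seq kit. The aligner, the counting program, its strand setting and the genome build are not given in the sources used here. For that reason no genome coordinates are given, and genes are named by the symbols in the deposited tables.

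The authors deposited a table of whole-number read counts for 21676 gene symbols in the 6 libraries, per the file headers. Each symbol had at least 1 count in some library. The authors also deposited a table of FPKM values for the same genes and libraries. Each of its 108650 values above 0 equalled the deposited count divided by the library's column total and by a single whole-number gene length, within a relative tolerance of 1e-06. The FPKM table is therefore a rescaling of the count table, and it was used only as an alternative unit. Columns were matched to samples by the names that the labels give them, and 0 columns were left without a sample.

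The counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3). Libraries were scaled by the trimmed mean of M-values (TMM), and genes were kept by filterByExpr with a minimum count of 10, which left 14629 genes. The tests were two-sided, p-values were adjusted by Benjamini-Hochberg over those genes, and the threshold was an adjusted p of 0.05. Each log2 fold change is ApoD overexpression over control, with a standard error computed from the fold change and its F statistic. Levels are CPM, counts scaled to a TMM-scaled library of 1000000, as mean ± SD over 3 libraries. For a gene with 1 to 3 counts in a group, the ratio is given with its 95% counting interval, which covers counting error only.

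Before the data were examined, 32 gene lists, the tests and the rule for named genes were fixed. Camera of limma 3.58.1 was run with a preset correlation of 0.01 on the 29 lists that had at least 5 tested members, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. The members of each list were also adjusted over the list alone. The rule named APOD, then the 10 largest rises and the 10 largest falls. These needed a mean count of at least 50, groups that did not overlap, and a symbol that is not a bare identifier, and XIST and Y-linked genes were left out. It then named up to 4 members past the threshold from each tested list, by the size of their change. The rule gave 134 genes, and the text gives the values of a part of them; some genes are not reported here. Any other gene whose value is printed was chosen after its values were seen.

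The test was first run on simulated counts of 14629 genes, with 200 changed genes and the means and library sizes of these samples. It recovered 47.8% of the 1.5-fold changes, 68.7% of the 2-fold changes and 90.9% of the 4-fold changes, with 11 false calls. Many more genes were called in the data, 7140, so these shares need not hold there. Totals of 37542568 to 40416964 counts per library leave relative counting error small for genes with many counts, and a group total of 3 counts was taken as the floor.

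The alternatives fixed beforehand were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no low-count filter, the replicate number as a block, and leaving out each library in turn. The others were a test against a 1.5-fold change with glmTreat and limma on log2(FPKM + 1) or log2(FPKM + 0.1). The FPKM tests used a filter of at least 1 FPKM in 3 libraries, and the first was also run without it. Chosen after seeing the data were offsets that remove each library's abundance trend, a fit limited to genes with a mean count of at least 500, and scaling by library totals alone. The 4 further gene lists in the closing section were also chosen after seeing the data.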

Results

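RNA sequencing was done on 6 libraries of the 83 cell line, which the submitters describe as a SACC cell. SACC usually stands for salivary adenoid cystic carcinoma, a tumour of the salivary glands. The series compared 3 control libraries with 3 libraries of cells that overexpress ApoD. Apolipoprotein D is a secreted lipocalin that binds arachidonic acid and other small lipids. How the gene was introduced and what the control cells received are not stated in the labels. The control libraries held 39434110, 39583565 and 38845545 counts, and the ApoD overexpression libraries 40416964, 37542568 and 39938592. The labels number the libraries of each group but do not say that they came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

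No 2 libraries were copies of each other. The chi-square per degree of freedom between libraries of 1 group ran from 11.6 to 39.5 over 6 pairs, and between groups from 94.4 to 206 over 9 pairs. The first principal component held 73.3% of the variance. It placed the controls at −36.9, −61.0 and −59.7 and the ApoD overexpression libraries at 42.8, 60.2 and 54.6, so that control replicate 1 lay nearest to the other group. Several properties of the libraries moved with the group. Genes with at least 1 count numbered 18643 ± 47.9 in controls and 17573 ± 206 with ApoD overexpression (SD, n = 3). Mitochondrially encoded genes took 4.35% ± 0.222 and 3.38% ± 0.178 of the counts. Genes with a mean count under 100 took 0.418% ± 0.0387 and 0.25% ± 0.0127. The 100 genes with the most counts took 20.1% ± 0.399 and 19.8% ± 0.556, a difference within the spread.

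The comparison asks which transcripts differ between cells with ApoD overexpression and controls. APOD itself had 9, 8 and 2 counts in the controls and 628, 528 and 625 counts with ApoD overexpression. Its level rose 99.4-fold, from 0.156 ± 0.0939 to 15.7 ± 0.752 CPM (SD, n = 3; log2 fold change 6.63 ± 0.29 SE, edgeR adjusted p = 6.31e-08). Of 20 epithelial junction genes 14 fell, among them CLDN1 and TJP3, and of 15 myoepithelial and basal genes 9 fell, among them KRT15. Of 19 mesenchymal genes 11 rose, among them SNAI2, TNC and AXL. Of 22 targets of the transcriptional co-activator YAP 13 rose, among them NT5E and again AXL, which stands in both lists. Among 14629 tested genes, 3539 rose and 3601 fell, which is 48.8% of those tested. All changes below are log2 fold changes ± SE unless a unit is named. Changes over 2-fold were fewer among the rises, 415, than among the falls, 1686.

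**Figure D1:**
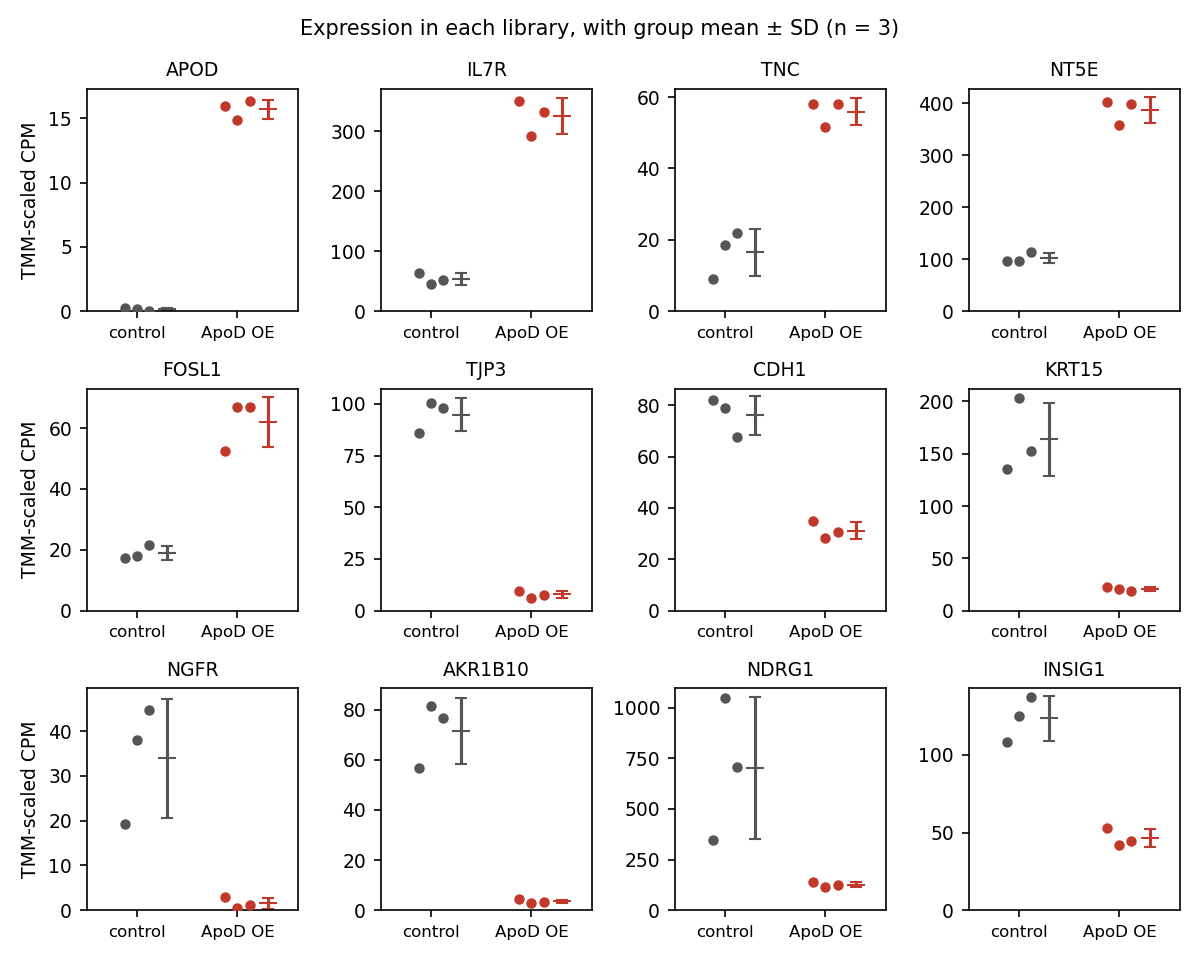
TMM-scaled CPM (vertical axes, each from 0) of 12 genes in the 3 control and 3 ApoD overexpression libraries; each point is a library, and the line with bars beside it is the group mean ± SD. The libraries of both groups do not overlap for any of the 12 genes, and NDRG1 ranged widely among the controls, with a mean of 699.6 ± 350.4 CPM. CDH1 was added after its values were seen.

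With ApoD overexpression APOD ranked 8364 by mean CPM, above 42.8% of the tested genes. A count per gene does not separate transcripts of an introduced copy from those of the cell's own gene. The libraries of both groups did not overlap for 8585 genes, 58.7% of those tested, where chance gives 10%.

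The largest rises after APOD were in APLN and ABCC9, with log2 fold changes of 4.08 ± 0.39 and 3.64 ± 0.32 (SE). APLN encodes the peptide hormone apelin and rose from 0.565 ± 0.409 to 9.60 ± 2.16 CPM (n = 3; edgeR adjusted p = 1.01e-05). KRT81, LINC01537, MYH15, AMTN, MARCHF4 and CALHM5 also rose, by 2.23 to 3.59 on the log2 scale. KRT81 belongs to a family of similar hair keratins, so its count can include reads of a relative. With 1 library left out some of these rises were larger by over 1.5 times: without control replicate 1 APLN rose by 4.82 and MYH15 by 3.25, without control replicate 2 LINC01537 rose by 4.02 and CALHM5 by 2.98, and without control replicate 3 KRT81 rose by 4.22. IL7R, a cytokine receptor chain, and SPOCK1, an extracellular proteoglycan, were abundant as well as changed. IL7R rose from 53.6 ± 9.79 to 324 ± 30.01 CPM (n = 3; log2 fold change 2.60 ± 0.13 SE, edgeR adjusted p = 1.44e-07). SPOCK1 rose from 108 ± 14.9 to 554 ± 45.7 CPM (n = 3; log2 fold change 2.36 ± 0.12 SE, edgeR adjusted p = 1.36e-07).

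The largest falls included ART1, which had 86, 323 and 232 counts in the controls and 1, 0 and 0 counts with ApoD overexpression, a ratio of 591 with a 95% counting interval of 106 to 23395; its only count with ApoD overexpression came from replicate 1. CP, which encodes the copper carrier ceruloplasmin, fell by 6.79 ± 0.50 (SE), and the membrane mucin MUC4 fell by 5.95 ± 0.40 on the log2 scale. With ApoD overexpression CP had only 2, 0 and 2 counts and MUC4 only 1, 3 and 6. At such counts an SE computed from the F statistic can be smaller than the counting error. PADI3 and PADI1, which convert arginine to citrulline in proteins, fell, with changes of −5.31 ± 0.38 and −5.04 ± 0.69. The protease KLK8, the BMP antagonist CHRD and the ectodysplasin receptor EDAR fell, with changes of −5.30 ± 0.44, −5.26 ± 0.34 and −4.99 ± 0.29. PELI2 and AGR2 fell, with changes of −4.96 ± 0.72 and −4.81 ± 0.38. Without ApoD overexpression replicate 3 the changes of PELI2, MUC4 and PADI1 were −7.41, −6.63 and −5.97, without replicate 1 that of AGR2 was −5.66, and without control replicate 3 that of PADI1 was −4.42. The highest edgeR adjusted p among these falls was 0.000174, for PELI2.

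**Figure D2:**
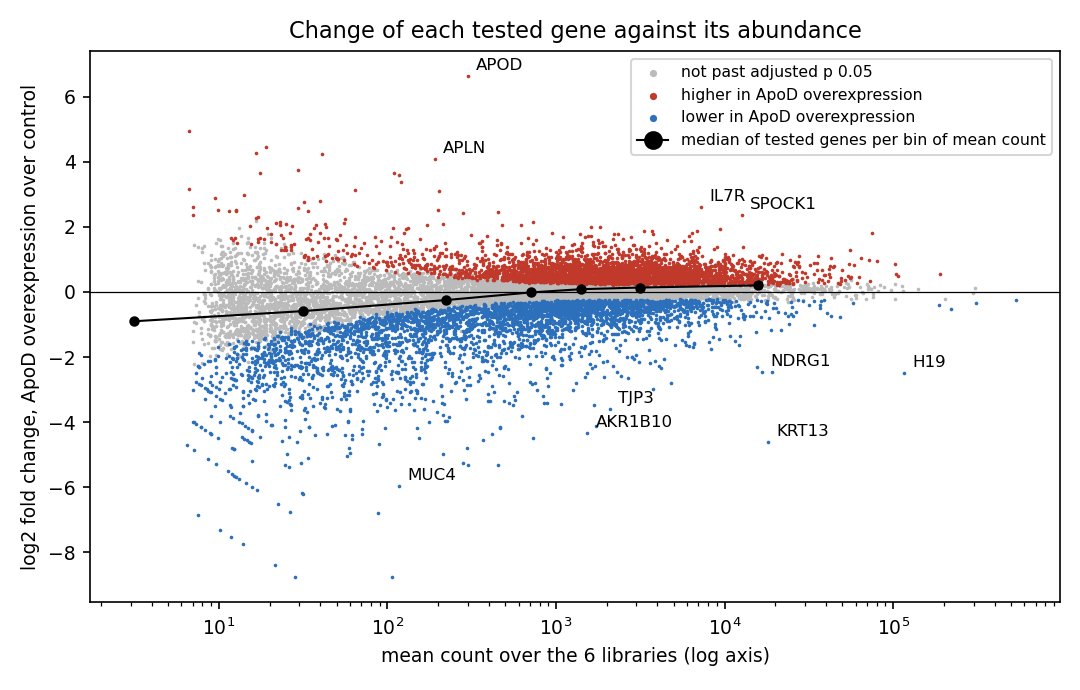
Log2 fold change of ApoD overexpression over control (vertical axis) against the mean count over the 6 libraries (horizontal, log axis) for the 14629 tested genes, with the median per bin of mean count as a black line. The 3539 genes that rose are red and the 3601 that fell are blue; the median runs from −0.90 for genes with a mean count of 1 to 10 to 0.20 for genes with 5000 or more. H19 and KRT13 were labelled after their values were seen.

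The change of a gene went with its abundance. The summed level of genes with a mean count of 1 to 10 with ApoD overexpression was 62.3% of that in controls. The share was 65.4% for 10 to 100 counts, 82.5% for 100 to 500 and 94.3% for 500 to 1000. It was 104% for 1000 to 2000 counts, 109% for 2000 to 5000 and 111% for 5000 or more. With scaling by library totals the median log2 fold change of all tested genes was −0.13 against −0.02 with TMM. That scaling called 2580 genes higher and 4435 lower, 36.8% higher against 49.6% with TMM.

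Epithelial junction genes fell as a group. Of 20 tested members 14 fell and 2 rose (14 and 2 adjusted over the list alone), with a median log2 fold change of −0.55 (camera adjusted p = 2.12e-06; adjusted p = 0.395 with an estimated correlation). TJP3, a tight junction scaffold, fell from 94.8 ± 7.83 to 7.87 ± 1.56 CPM (n = 3; log2 fold change −3.59 ± 0.14 SE). The claudins CLDN3, CLDN1 and CLDN7 fell, with changes of −2.40 ± 0.35, −1.94 ± 0.13 and −1.71 ± 0.12. CDH1, which encodes E-cadherin and was picked out after its value was seen, fell from 76.1 ± 7.60 to 31.2 ± 3.48 CPM. The members that rose were PKP3, a desmosome protein, and ESRP2, a splicing regulator, both also picked out after their values were seen.

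Mesenchymal and EMT genes moved the other way, with 11 of 19 tested members higher and 2 lower (12 and 2 adjusted over the list alone). Their median log2 fold change was 0.83 (camera adjusted p = 0.000249; adjusted p = 0.297 with an estimated correlation). TNC, an extracellular matrix glycoprotein, rose from 16.5 ± 6.69 to 55.9 ± 3.78 CPM (n = 3). SNAI2 and ZEB1, transcription factors that repress E-cadherin, rose by 1.36 ± 0.11 and 1.20 ± 0.30 (SE) on the log2 scale, and the receptor kinase AXL by 1.13 ± 0.14. Among the members that fell was LOX, a collagen cross-linking enzyme, named after its value was seen.

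Myoepithelial and basal genes fell in 9 of 15 tested members and rose in 1 (10 and 1 adjusted over the list alone). The median was −0.47 (camera adjusted p = 0.00954; adjusted p = 0.634 with an estimated correlation). KRT15 fell from 164 ± 35.2 to 20.7 ± 1.82 CPM (n = 3; log2 fold change −2.98 ± 0.15 SE). MYLK, KRT14 and the basal transcription factor TP63 fell, with changes of −1.76 ± 0.27, −1.75 ± 0.21 and −1.05 ± 0.13, where KRT14 can share reads with other keratins. The list call was lost with unfiltered FPKM (adjusted p = 0.0624; range over the alternatives 0.000352 to 0.634). Salivary luminal and secretory genes were mixed, with 2 of 10 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.241). EHF, KRT19 and MUC1 fell, with changes of −3.35 ± 0.31, −2.46 ± 0.36 and −1.47 ± 0.10, and SOX9 rose by 0.72 ± 0.21. The median of this list, 0.05, had the opposite sign to its mean, −0.64, and to camera's direction, and it was −0.07 with library totals.

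Targets of YAP and TEAD rose in 13 of 22 members and fell in 3, with the same counts adjusted over the list alone. The median was 0.64 (camera adjusted p = 0.000138; adjusted p = 0.539 with an estimated correlation). NT5E, the ectonucleotidase CD73, rose from 102 ± 10.5 to 387 ± 24.98 CPM (n = 3; log2 fold change 1.92 ± 0.10 SE), and FJX1 rose from 19.4 ± 1.40 to 55.0 ± 7.47 CPM. MAPK output and immediate early genes rose in 10 of 23 members and fell in 6, also when adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.0375; adjusted p = 0.634 with an estimated correlation), against 0.14 with library totals and 0.38 with the abundance trend removed. FOSL1, an AP-1 subunit, rose by 1.71 ± 0.13 and the feedback inhibitor SPRY4 by 1.57 ± 0.32, while the immediate early factor EGR1 fell by 2.36 ± 0.25. Without control replicate 1 the MAPK call was lost (camera adjusted p = 0.150; range over the alternatives 0.00192 to 0.634), and it was also lost on FPKM, at up to 0.177. TGF-beta and SMAD targets rose in 7 of 19 members and fell in 5, also adjusted over the list alone (camera adjusted p = 0.520), and with library totals 5 rose and 5 fell. TGFBI rose by 0.83 ± 0.09, and the cell cycle inhibitor CDKN2B fell by 1.31 ± 0.15.

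**Figure D3:**
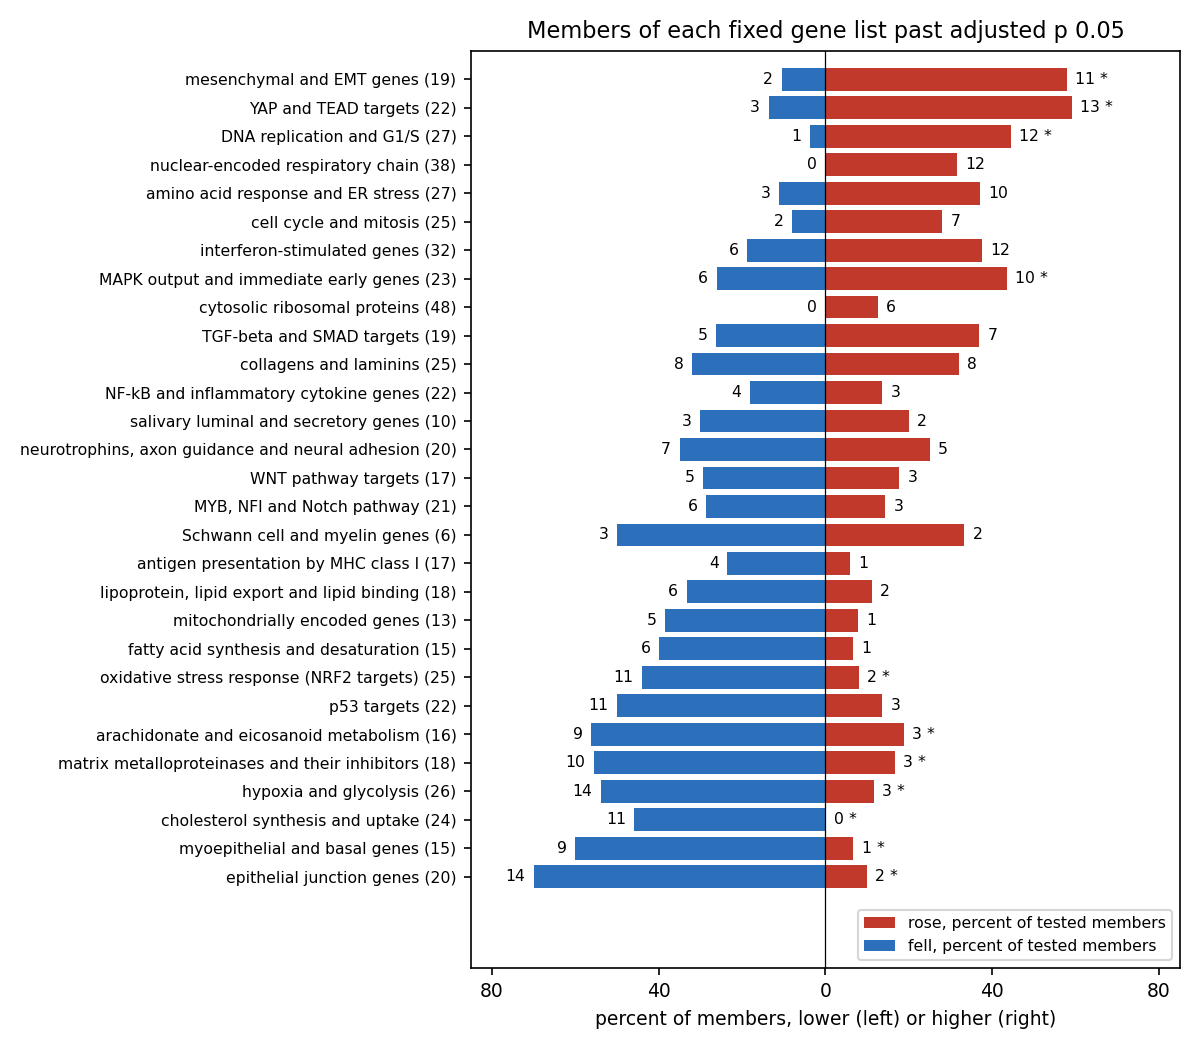
Share of the tested members of each of the 29 tested lists that fell (left, blue) or rose (right, red) past an edgeR adjusted p of 0.05, in percent, with the number of members beside each bar and the number tested in brackets. An asterisk marks the 11 lists past a camera adjusted p of 0.05 with the preset correlation, 4 up and 7 down; 0 of them passed with an estimated correlation. With library totals or with the abundance trend removed, some cytosolic ribosomal protein and respiratory chain genes fell.

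DNA replication and G1/S genes rose in 12 of 27 members and fell in 1, also adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.0124; adjusted p = 0.634 with an estimated correlation). It was 0.07 with library totals and 0.02 with the abundance trend removed, and 9 rose and 2 fell under each. CCND1, which encodes cyclin D1 and also stands in the MAPK list, rose from 75.4 ± 7.38 to 176 ± 17.0 CPM (n = 3). MCM10 and UHRF1 rose by 0.78 ± 0.16 and 0.74 ± 0.11 (SE). The list call was lost on filtered FPKM (adjusted p = 0.0952), with the abundance trend removed (0.269) and for genes with a mean count of at least 500 (0.183), in a range over the alternatives of 0.00129 to 0.634. Cell cycle and mitosis genes rose in 7 of 25 members and fell in 2, also adjusted over the list alone (camera adjusted p = 0.187). The mitotic regulators FOXM1, CDC20 and PLK1 rose by 0.79 ± 0.12, 0.78 ± 0.12 and 0.76 ± 0.10, and TOP2A fell by 0.60 ± 0.17. The median of this list was 0.02 with TMM, −0.09 with library totals (6 rose and 4 fell) and −0.06 with the abundance trend removed (6 rose and 5 fell).

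Nuclear-encoded respiratory chain genes rose in 12 of 38 members and fell in 0, also adjusted over the list alone (camera adjusted p = 0.0697). With the abundance trend removed 7 rose and 6 fell, and with library totals 8 rose and 4 fell. NDUFC2 and ATP5MC1 rose by 0.62 ± 0.16 and 0.57 ± 0.12 (SE). Camera called this list higher without ApoD overexpression replicate 1 (adjusted p = 0.0273) or replicate 3 (0.0121), with no low-count filter (0.0123) and by the DESeq2 Wald test (0.0320), in a range over the alternative fits of 0.0121 to 0.943 (adjusted p = 0.793 with an estimated correlation). Cytosolic ribosomal proteins rose in 6 of 48 members and fell in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.178), against 1 and 9 with the abundance trend removed and 3 and 2 with library totals. RPL23 rose by 0.41 ± 0.10, and processed pseudogenes can share its reads. The ribosomal list was called higher without ApoD overexpression replicate 1 (adjusted p = 0.0478) or replicate 3 (0.0404), in a range over the alternative fits of 0.0404 to 0.843 (adjusted p = 0.859 with an estimated correlation). Mitochondrially encoded genes fell in 5 of 13 members and rose in 1, also adjusted over the list alone (camera adjusted p = 0.504). This list was called lower with the abundance trend removed (9 fell, adjusted p = 0.0471), in a range over the alternative fits of 0.0471 to 0.822 (adjusted p = 0.833 with an estimated correlation), and 8 fell with library totals. ND4 fell by 0.54 ± 0.10 and ND1 rose by 0.52 ± 0.10, beside the lower share of mitochondrial counts given for the ApoD overexpression libraries. ND4 overlaps ND4L, and nuclear copies can share reads of both.

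Cholesterol synthesis and uptake genes fell in 11 of 24 members and rose in 0, also adjusted over the list alone. Their median was −0.25 (camera adjusted p = 0.0336; adjusted p = 0.634 with an estimated correlation). INSIG1, which holds back sterol synthesis, fell from 124 ± 14.7 to 46.5 ± 5.71 CPM (n = 3; log2 fold change −1.41 ± 0.12 SE). The sterol synthesis enzymes MSMO1 and FDFT1 fell, with changes of −0.87 ± 0.17 and −0.73 ± 0.09. The cholesterol call was lost without control replicate 1 (adjusted p = 0.0882) or replicate 3 (0.0524) and without ApoD overexpression replicate 1 (0.0526) or replicate 3 (0.0642), in a range over the alternatives of 0.00110 to 0.634. Fatty acid synthesis and desaturation genes fell in 6 of 15 members and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.178). Camera called this list lower with the abundance trend removed (adjusted p = 0.00830), for genes with a mean count of at least 500 (0.0454) and on unfiltered FPKM (0.0369), in a range over the alternative fits of 0.00830 to 0.296 (adjusted p = 0.662 with an estimated correlation). The desaturase SCD fell from 1534 ± 93.3 to 908 ± 39.7 CPM, and ACLY rose by 0.52 ± 0.11. Lipoprotein, lipid export and lipid binding genes fell in 6 of 18 members and rose in 2, also adjusted over the list alone (camera adjusted p = 0.241). LCN2, a lipocalin like ApoD, fell by 3.20 ± 0.27, and the lipoprotein receptor VLDLR fell by 2.30 ± 0.48.

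Arachidonate and eicosanoid genes fell in 9 of 16 members and rose in 3, also adjusted over the list alone. Their median was −0.71 (camera adjusted p = 0.0348; adjusted p = 0.395 with an estimated correlation), and −0.45 with the abundance trend removed. HPGD, which inactivates prostaglandins, fell from 31.0 ± 8.60 to 4.33 ± 0.701 CPM (n = 3; log2 fold change −2.84 ± 0.21 SE). CYP4F3, which inactivates leukotriene B4 and has close relatives in the genome, fell by 2.73 ± 0.22, and the lipoxygenase ALOX5 fell by 2.30 ± 0.24. PTGIS had 16, 12 and 17 counts in the controls and 0, 0 and 2 counts with ApoD overexpression, a ratio of 20.8 with a 95% counting interval of 5.42 to 177, and without ApoD overexpression replicate 3 no count was left in that group. The arachidonate call by camera was lost without ApoD overexpression replicate 2 (adjusted p = 0.0662) or replicate 3 (0.0508) and with library totals (0.0516). It was also lost for genes with a mean count of at least 500 (0.243) and on FPKM (up to 0.318). The range over the alternatives ran from 0.00630, which fry gave, to 0.395, which camera gave with an estimated correlation.

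Targets of the oxidative stress factor NRF2 fell in 11 of 25 members and rose in 2 (12 and 2 adjusted over the list alone). The median was −0.27 (camera adjusted p = 0.000999; adjusted p = 0.395 with an estimated correlation). The aldo-keto reductase AKR1B10 fell from 71.4 ± 13.1 to 3.54 ± 0.703 CPM (n = 3; log2 fold change −4.33 ± 0.18 SE). AKR1C2 and AKR1C1 fell, with changes of −3.77 ± 0.28 and −2.50 ± 0.22, but these near-identical genes can share reads. GPX2, a glutathione peroxidase, fell by 3.47 ± 0.15. The widely used NRF2 targets NQO1 and GCLM, picked out after their values were seen, had log2 fold changes of 0.21 and 0.23 and did not pass.

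Hypoxia and glycolysis genes fell in 14 of 26 members and rose in 3, also adjusted over the list alone. The median was −0.64 (camera adjusted p = 0.0102; adjusted p = 0.681 with an estimated correlation, and 0.0830 by fry). CA9, a carbonic anhydrase induced by low oxygen, fell by 2.67 ± 0.42 (SE), and NDRG1, ALDOC and ENO2 fell, with changes of −2.47 ± 0.29, −2.08 ± 0.27 and −2.02 ± 0.25. These genes also varied among the controls, where NDRG1 had 13991, 42908 and 29165 counts and CA9 had 94, 335 and 238. The members that rose were PFKP, PGAM1 and LDHA, which encode glycolytic enzymes. Targets of p53 fell in 11 of 22 members and rose in 3 (11 and 4 adjusted over the list alone; camera adjusted p = 0.114). TP53INP1 and GDF15 fell, with changes of −2.46 ± 0.38 and −1.71 ± 0.19, and the nuclease AEN rose by 1.69 ± 0.16. Amino acid response and ER stress genes rose in 10 of 27 members and fell in 3, also adjusted over the list alone (camera adjusted p = 0.184), and with library totals 8 rose and 5 fell and with the abundance trend removed 7 and 5. ATF5 and the serine synthesis enzyme PSAT1 rose by 1.65 ± 0.20 and 1.18 ± 0.12, and DDIT4 fell by 1.18 ± 0.13.

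Matrix metalloproteinases and their inhibitors fell in 10 of 18 members and rose in 3 (12 and 4 adjusted over the list alone). Their median was −0.37 (camera adjusted p = 0.00948; adjusted p = 0.634 with an estimated correlation), and −0.56 with the abundance trend removed. The collagenases MMP13 and MMP1 fell, with changes of −3.35 ± 0.28 and −2.48 ± 0.17 (SE), and MMP1 went from 64.4 ± 17.7 to 11.5 ± 0.362 CPM (n = 3). MMP11 and MMP10 fell, with changes of −2.89 ± 0.52 and −2.82 ± 0.50, where MMP10 had −3.50 without ApoD overexpression replicate 1. The members that rose were the inhibitor TIMP1, ADAM12 and the urokinase receptor PLAUR, and the call was lost on filtered FPKM (adjusted p = 0.0796; range over the alternatives 0.000315 to 0.634). Collagens and laminins were split, with 8 of 25 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.840). The fibrillar collagens COL3A1 and COL1A1 fell, with changes of −4.52 ± 0.48 and −1.21 ± 0.15, and the basement membrane collagen COL4A2 rose by 0.88 ± 0.08. The median of this list was 0.02, against a mean of −0.16 and a median of −0.09 with library totals.

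Interferon-stimulated genes rose in 12 of 32 members and fell in 6, also adjusted over the list alone (camera adjusted p = 0.147). Their median was 0.04, against −0.08 with library totals and 0.02 with the abundance trend removed. RSAD2, IFI44, HERC6 and IFIT1, antiviral effectors, rose by 1.81 ± 0.20, 1.56 ± 0.14, 1.41 ± 0.25 and 1.37 ± 0.19 (SE). The members that fell included OAS1, PARP9 and the signalling factors STAT2, IRF7 and IRF9. The interferon list was called higher by camera without control replicate 1 (adjusted p = 0.00165) or ApoD overexpression replicate 3 (0.0402). It was also called higher with no low-count filter (0.0123) and with the replicate number as a block (0.0164). The range over the alternative fits was 0.00165 to 0.397 (adjusted p = 0.754 with an estimated correlation). Antigen presentation genes of MHC class I fell in 4 of 17 members and rose in 1, also adjusted over the list alone (camera adjusted p = 0.852), while 8 fell with library totals and 7 with the abundance trend removed. TAP2 rose by 1.06 ± 0.11, and HLA-F and HLA-E, members of a family with shared sequence, fell, with changes of −0.66 ± 0.13 and −0.60 ± 0.12. NF-kB and inflammatory cytokine genes fell in 4 of 22 members and rose in 3, also adjusted over the list alone (camera adjusted p = 0.517). CCL5 and TNFAIP2 fell, with changes of −1.57 ± 0.15 and −1.36 ± 0.09. The median of the NF-kB list was −0.00, against 0.13 with the abundance trend removed and −0.13 with library totals.

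Genes of neurotrophins, axon guidance and neural adhesion fell in 7 of 20 members and rose in 5, also adjusted over the list alone (camera adjusted p = 0.241). NGFR, the low-affinity neurotrophin receptor, fell from 34.0 ± 13.3 to 1.51 ± 1.28 CPM (n = 3; log2 fold change −4.47 ± 0.47 SE, and −5.37 without ApoD overexpression replicate 1). NRTN, which encodes neurturin, fell by 3.64 ± 0.26, and SEMA3C fell by 1.43 ± 0.13. Schwann cell and myelin genes fell in 3 of 6 members and rose in 2, also adjusted over the list alone (camera adjusted p = 0.520). PRX and ERBB3 fell, with changes of −1.86 ± 0.28 and −1.54 ± 0.28, and PMP22 rose by 0.59 ± 0.14. In the MYB, NFI and Notch list 6 of 21 members fell and 3 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.546), and with library totals 10 fell and 2 rose. The Notch target HES1 and the co-activator MAML2 fell, with changes of −1.21 ± 0.17 and −1.01 ± 0.15. WNT pathway targets fell in 5 of 17 members and rose in 3, also adjusted over the list alone (camera adjusted p = 0.840). The receptor FZD7 fell by 0.79 ± 0.13 and the WNT antagonist DKK1 rose by 0.75 ± 0.15. The median of the WNT list was 0.14, against 0.03 with library totals and a mean of −0.10, and with the abundance trend removed 2 members fell and 4 rose.

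Markers of other cell types had too few tested members for a list test. Of the fibroblast markers, COL1A2, DCN and LUM had means of at most 0.333 counts per library in either group, and 3 of 4 tested markers fell (4 adjusted over the list alone). Others were not near 0. FBLN1 had means of 6503 counts in controls and 2878 with ApoD overexpression, and COL1A1 had 1073 and 429. Among endothelial markers 3 of 4 tested fell, also adjusted over the list alone. PECAM1 went from a mean of 285 to 52.7 counts, VWF from 107 to 14.7 and CDH5 from 52.3 to 0.333, with its only count under ApoD overexpression in replicate 1. Leukocyte markers were near 0, with PTPRC at 4.33 and 0 counts, apart from CD68 and CSF1R at means of 1043 and 233 counts in controls. CD68 rose by 0.57 ± 0.21 (SE), with 1 rise and 0 falls among 2 tested leukocyte markers (1 and 1 adjusted over the list alone). This call was lost with library totals (0.44 ± 0.22, adjusted p = 0.126; 0 rose and 1 fell) and with the abundance trend removed (0.52 ± 0.21, adjusted p = 0.0574; 0 rose and 0 fell), with a smaller change in each.

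Of the 11 list calls by camera with the preset correlation, 0 held with an estimated correlation, where the smallest adjusted p was 0.297. The mesenchymal and arachidonate calls were lost too, although their estimated correlations, −0.004 and −0.009, lay below the preset 0.01. With an estimated correlation the test takes its degrees of freedom from the 6 libraries, which leaves it little power. Its 0 calls therefore do not decide whether correlation between members undoes the preset calls. Fry asks whether the genes of a list move on balance 1 way and does not compare them with other genes. By fry 18 lists passed, including 10 of these 11, and 28 passed when members may move either way. With 48.8% of all tested genes changed, such passes do not bear on the camera calls. Without control replicate 1, the control nearest to the other group, 7519 genes passed, 3712 higher and 3807 lower, and 10 lists.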

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

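The alternatives with abundance-trend offsets, genes of a mean count of at least 500 and library totals were chosen only after the result was seen. APOD stayed higher in each fit that tested it, with a log2 fold change of 6.22 to 6.98 with 1 library left out, and it was not in the fit to genes with a mean count of at least 500. The count of changed genes was 5454 to 7519 with 1 library left out, with 2690 to 3712 higher, 2764 to 3807 lower, 10 to 12 lists and 123 to 132 of the 134 named genes. It was 7156 with DESeq2 size factors, 7308 by DESeq2, 7347 with no low-count filter and 6622 with the abundance trend removed. Against a change of 1.5-fold, glmTreat called 1975 genes, 545 higher and 1430 lower, and 93 named genes, because this test asks for a larger change. On log2(FPKM + 1) 7 lists passed and on log2(FPKM + 0.1) 7 lists, of which the cause was not tested. With the FPKM filter 43.1% of the called genes were higher in both. Without it 2317 genes were higher and 3948 lower, 37.0% higher. FPKM is scaled by library totals without TMM, and counts scaled by library totals gave a similar 36.8% higher. Whether other causes add to this shift was not tested. Among genes with a mean count of at least 500, scaled and tested on their own, 2394 were higher and 2367 lower. In the main fit 459 of these genes rose and 543 fell at a mean count of 500 to 1000. There 812 rose and 552 fell at 1000 to 2000, 1077 and 475 at 2000 to 5000, and 765 and 229 at 5000 or more. The balance of rises and falls among abundant genes therefore differed between these fits. Of the 74 named genes in the limited fit 73 passed, and the other named genes were not tested in it. Camera with an estimated correlation called 0 lists and fry 18, which differ from the preset correlation in the test itself.

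With the replicate number as a block, 6348 genes passed, 3088 higher and 3260 lower, with 129 named genes and 12 lists, 1 more because the interferon list was called higher (adjusted p = 0.0164). The numbers gave no sign that they pair the libraries, though with 3 libraries per group this check is weak. Deviations of same-numbered libraries from their group means correlated at −0.12, −0.01 and −0.04, and 0 of 6 libraries correlated best with their own number.

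Over 133 named genes other than APOD, 2019 of 2140 values under the alternatives kept direction and threshold, 121 lost the threshold and 0 reversed. The losses were in 43 genes, of which 41 were lost with glmTreat. Leaving out a single library ended 12 of these calls, for CD36, DLL4, EGR3, FOXD3, HEY1, LTBP2, NLRC5, NOTUM, RPL5, SPATA18, TCF7 and TGFB2. Depth limits the genes with few counts. In simulated data with 200 changed genes 47.8% of 1.5-fold changes were recovered, a share that need not hold where 7140 genes were called.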

Other observations

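The 4 lists described next, and the tests below of sequencing depth, of a few genes taking the counts, of a background spread evenly by gene length, of the abundance trend and of a mixture, were chosen only after the result was seen. The lists were made after the changes of single genes were seen, so their counts and medians describe these genes and no test against other genes is given. All 50 tested members of a list of ribosome biogenesis and nucleolar genes rose (50 adjusted over the list alone), with a median log2 fold change of 1.06. RRP9, a component of the small subunit processome, rose from 16.7 ± 2.26 to 67.4 ± 11.2 CPM (SD, n = 3), and BOP1, needed for large subunit assembly, from 59.0 ± 16.5 to 177 ± 22.5 CPM. Of 26 genes of polyamine, nucleotide and folate synthesis 21 rose and 0 fell (22 and 0 adjusted over the list alone). ODC1, the first enzyme of polyamine synthesis, rose by 1.88 ± 0.21 (SE) and the spermidine synthase SRM by 1.88 ± 0.18 on the log2 scale.

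Squamous differentiation genes fell in 23 of 28 tested members and rose in 1, KRT6A, which can share reads with near-identical keratins, also adjusted over the list alone. Their median was −2.67. KRT13, a keratin of stratified mucosa, fell from 853 ± 123 to 35.1 ± 4.93 CPM (n = 3), and TMPRSS4, a membrane protease, fell by 4.37 ± 0.47 (SE). Mucins and secreted glandular genes fell in 10 of 12 members and rose in 1, MUC13, also adjusted over the list alone, with a median of −2.69. MUC5B fell by 3.12 ± 0.39. The imprinted noncoding RNA H19 fell from 4887 ± 510.2 to 873 ± 95.6 CPM (n = 3; edgeR adjusted p = 8.23e-08).

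Genes with few counts were lower in the ApoD overexpression libraries. Depth is argued against, because after thinning each library to the smallest total the summed count of genes with a mean count under 100 was still 59.9% of that in controls, and genes with a count numbered 18597 ± 53.8 and 17516 ± 162. The median log2 fold change of genes with a mean count of 500 to 2000 was 0.0435. TMM holds such a median near 0, so it does not decide on a few genes taking the counts. That cause would lower all other genes by the same factor. It is argued against, because the summed level was 65.4% of controls for 10 to 100 counts and 94.3% for 500 to 1000. The 100 genes with the most counts also took no larger share, 19.8% ± 0.556 against 20.1% ± 0.399 in controls. A background of reads in the controls spread evenly by gene length is argued against as the whole cause, because the 3063 genes with a mean count of 10 to 100 lost at least 0.0706 CPM per kb from any control, 1.94 times the largest level in any control, 0.0364 CPM per kb, of the 4098 genes with a mean count of 1 to 10. An earlier test for a uniform background does not decide: changes scattered 2.55 times as much between groups as between controls (chi-square per degree of freedom 11.4 against 4.47), but added reads would also lower genes unequally, so the bound set for that test was wrong. An uneven background, such as from genomic DNA or unspliced RNA, and a wider loss of lowly expressed transcripts with ApoD overexpression both stay open, and neither was tested.

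Squamous differentiation genes were lower and nucleolar genes higher with ApoD overexpression. With the abundance trend removed the medians were −2.14 for squamous and 0.914 for nucleolar genes, so these members changed beyond that trend. The members were picked after their changes were seen, so this outcome was close to fixed beforehand. It therefore does not decide on the abundance trend as a cause. Without any 1 library the medians kept at least 0.935 of their size, so neither median rested on a single library. Picking members by their changes also favours this outcome. A difference between cell populations that was already there when the cells were made, such as an outgrowth of some cells, stays open, as does an effect of ApoD itself, and neither was tested. A difference in culture state between the groups also stays open and was not tested. Some squamous genes varied among the controls, where PADI3 had 438, 1167 and 1037 counts and KLK8 had 304, 765 and 691. KRT13 varied less, with 31265, 40758 and 32654 counts.

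Control replicate 1 lay nearest to the ApoD overexpression libraries. A mixture with ApoD overexpression material is argued against by APOD, because a share of 24.1%, the median over 600 other changed genes, needs 153 APOD counts in that library, while 9 were counted, with an upper 95% limit of 17.1. That share was uneven between genes, with quartiles of 13.6% and 37.4%. Culture state and library preparation stay open, and neither was tested.

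The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7140 changed genes and the highest of the other splits 1. In a single direction the real split gave 3539 and 3601 genes, and the highest count of the others in either direction was 1. Each of the other splits mixes both groups, so the difference between the groups adds to the spread within them. Few gene calls were therefore likely beforehand in those splits and give no support to the real one. For the gene lists the real split gave 11 calls and the others 4 to 9, although these others called at most 1 gene. The number of list calls thus set the real split apart far less than the number of genes.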
